A study of Mus musculus with 35 samples.

How the data were processed

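Total RNA from flow-sorted immune cells of male C57BL/6J mice was hybridised, 1 sample per array, to 35 Affymetrix Mouse430_2 arrays. The deposited values are log2 expression values per probe set, 1 column per array, normalised by the authors to a near-common distribution. That the base of the logarithm is 2 was inferred from the range, 2.30 to 16.02, and the processing method is not recorded. All arrays shared the same minimum of 2.30, at which 43.6% to 48.3% of the probe sets of each array lay. Array medians ran from 2.31 to 2.39 and upper quartiles from 6.09 to 6.56. A plain difference of means against a group at this floor is a lower bound, and a fitted difference is not. For arrays there is no depth to give, and the number of arrays limits the precision.

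The table held 45101 probe sets. The 64 control probe sets, 9160 probe sets without a gene symbol and 932 with several symbols were left out, and 34945 with 1 symbol were kept. Of these, 34754 had an Entrez identifier that matched the reference gene table (assembly GRCm38.p6, used for names only). Each of the 18193 genes was represented by its probe set with the highest mean over the 35 arrays. For 9010 genes there was more than 1 probe set to choose from. A single missing value, of a Golga7 probe set, was left as missing.

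Groups were taken from the sample titles. The first model held 20 arrays: inflammatory monocytes, SatM, cMoP, SMP, GMP, MDP, basophils, eosinophils and neutrophils, with a term for cell type and 1 term for the cMoP and SMP arrays titled WT. The second model held the 15 arrays of a tissue panel, with terms for cell type and tissue. Fitted differences are therefore not always the plain difference of group means. In the first model this concerns comparisons of cMoP or SMP with groups other than these 2. In the second model it concerns all comparisons. Genes were kept where at least 2 arrays of the model lay over that array's median, which left 12077 genes in the first model and 11733 in the second. Residual degrees of freedom were 10 and 6. Models were fitted with limma 3.58.1 (lmFit, and eBayes with trend) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. Every adjusted p of a gene comes from limma's moderated test. Tables and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

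There were 33 gene lists, tested in each comparison with camera (limma) at a preset correlation between genes of 0.01, adjusted over the lists of the comparison. The test was repeated with the correlation estimated from the data, and that adjusted p is given where it ended a call. Lists of blood and progenitor cells were sort and lineage surface markers, primary granule, secondary and tertiary granule, mature neutrophil, basophil and mast cell, eosinophil, classical monocyte, nonclassical monocyte, dendritic cell, stem and progenitor, and myeloid transcription factor genes. Lists of macrophages and their states were tissue macrophage, alveolar macrophage, alternative activation, fibrosis-associated, inflammatory cytokine and chemokine, MHC class II presentation, interferon-stimulated, Toll-like and Fc receptor, and lysosome and phagocytosis genes. Lists of general functions were cell cycle, ribosome biogenesis, oxidative phosphorylation, glycolysis, cholesterol synthesis, and immediate-early and stress genes. Lists of other cells that a sort can hold were B cell, T cell, NK cell, erythroid, megakaryocyte and platelet, stromal, and lung epithelium genes. Counts of called members are given over all genes and adjusted over the list alone.

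The comparisons, their models and tests, the lists and the rule for named genes were fixed before the data were examined. The rule named, per comparison, the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups, up to 4 called members of each list that was called or had at least 3 called members, and always the sort and lineage surface genes and Cebpb. After the values were seen, the genes in the text were narrowed to those whose call was the same when each array of the compared groups was left out in turn. Genes given without alternatives are outside this narrowing. Rule genes whose call changed only under another alternative are given in the text with that change. The text gives a choice of the genes and of the called lists, made after the values were seen. The comparison of SMP with basophils was added after the values were seen.

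Alternatives fixed before the data were examined were quantile normalisation of the 35 arrays, no filter on dim genes, a filter at the 60th percentile, the mean of a gene's probe sets, every probe set tested by itself, a fit of the compared groups alone, eBayes without trend and with robust estimation, no fold threshold, the replicate number in the titles as a block, no tissue term, no term for the WT-titled set, a fit without the 4 WT-titled arrays, the 4 WT-titled arrays alone, the bone marrow SatM array of the panel added to the other SatM arrays, an estimated correlation between list genes, the top 200 genes per direction as signature, and leaving out each array in turn. Alternatives chosen after the data were seen were a filter at log2 5 in at least 2 arrays and a fit without the 4 lung arrays. Other pseudocounts would apply to linear values only and were not run.

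The models were tested on simulated data with the same groups. Each gene had 1 mean over all arrays and independent normal noise at its fitted spread. Changes were placed only in genes with a mean over log2 6. Tissue, set and other cell-type differences and correlation between genes were left out. The shares and false calls below hold for that simpler setting and need not hold for these arrays. For SatM against inflammatory monocytes (12077 genes), 7.5%, 55.2% and 92.4% of genes with a true log2 change of 1, 2 and 4 were called. For SMP against cMoP (12077 genes) the shares were 16.4%, 80.6% and 100%. In the panel, for SatM against Msr1-negative Ceacam1-negative cells (11733 genes), they were 3.0%, 43.3% and 89.4%. In each of these simulations 0 genes were called in the wrong direction, and 5, 7 and 6 unchanged genes were called. GMP and MDP had 1 array each and the lung macrophage arrays came from differently titled sorts, so their values are given without a test. The second model still held the 2 lung macrophage arrays as 1 group, so the difference between them enters the error of all panel tests.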

Results

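Gene expression was measured on 35 arrays in cells sorted by flow cytometry from the bone marrow, spleen, blood and lung of male mice. SatM (segregated-nucleus-containing atypical monocytes, which the labels tie to fibrosis) and inflammatory monocytes of the bone marrow were measured on 2 arrays each. Their named progenitors, SMP for SatM and cMoP (the common monocyte progenitor), were measured on 4 arrays each, of which 2 were titled WT. GMP (granulocyte-monocyte progenitors) and MDP (monocyte-dendritic cell progenitors) had 1 array each. Basophils, eosinophils and neutrophils of the spleen had 2 arrays each. A separate panel held SatM from spleen, bone marrow, blood and lung (4 arrays), cells negative for the sort markers Msr1 and Ceacam1 from spleen, bone marrow and blood (3 arrays), other Ly6C-negative cells from spleen and blood (2 arrays), Msr1-dull Ceacam1-dull cells from bone marrow and lung (2 arrays), M2-like macrophages from spleen and bone marrow (2 arrays) and lung macrophages (2 arrays). Replicates correlated across genes at Pearson r = 0.983 for SatM, 0.997 for inflammatory monocytes, 0.963 to 0.996 for cMoP and 0.927 to 0.970 for SMP. Genes are not independent replicates.

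**Figure D1:**
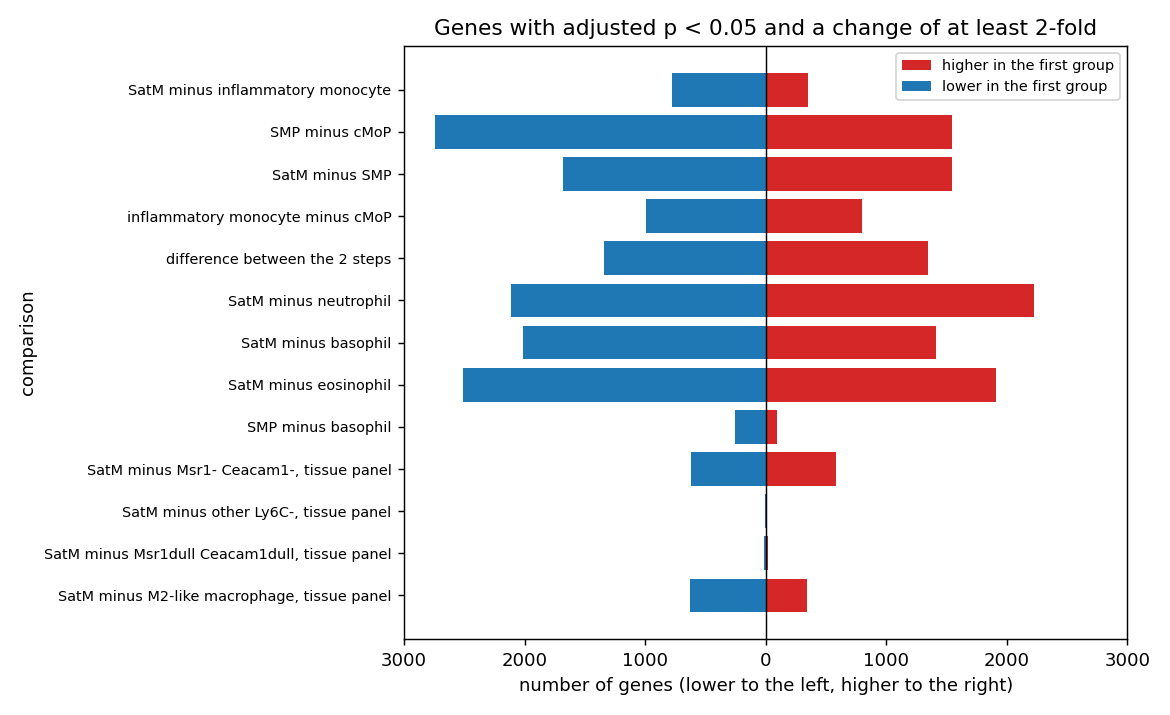
Number of genes called per comparison (bars to the right, higher in the first group; bars to the left, lower in the first group; x axis, number of genes). The counts ran from 8 (SatM against other Ly6C-negative cells) to 4429 (SatM against eosinophils).

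The comparison of SatM with inflammatory monocytes asked what sets SatM apart among bone marrow monocytes. SatM held more mRNA of surface molecules and regulators of patrolling (nonclassical) monocytes. The Fc receptor gene Fcgr4 measured 13.55 ± 0.21 (SD, n = 2) in SatM and 8.51 ± 0.21 (SD, n = 2) in inflammatory monocytes (log2 difference 5.03, adjusted p = 1.76e-05). The integrin gene Itgax (5.89, adjusted p = 0.00262), the lipid scavenger receptor gene Cd36 (5.52, adjusted p = 2.75e-05) and the nuclear receptor gene Pparg (4.28, adjusted p = 2.03e-07) were higher too. The transcription factor gene Pou2f2 was higher by 2.53 (adjusted p = 0.00261). The classical monocyte genes F13a1, Fn1 and Vcan were far lower in SatM, while others such as Csf1r (14.46) and Klf4 (13.12) were measured there at high levels. The clotting factor gene F13a1 measured 2.42 ± 0.03 (SD, n = 2) against 13.66 ± 0.09 (SD, n = 2), a log2 difference of -11.23 (adjusted p = 3.48e-09). Fibronectin (Fn1) differed by -9.83 (adjusted p = 5.87e-07), and versican (Vcan), at the floor in both SatM arrays, was at least 403-fold lower (adjusted p = 6.56e-06).

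Eosinophil granule genes were measured in SatM and lay at the floor in both inflammatory monocyte arrays. Prg2, which encodes major basic protein, reached 12.10 ± 0.84 (SD, n = 2) in SatM and was at least 891-fold higher (adjusted p = 1.91e-05). Eosinophil peroxidase (Epx) was at least 190-fold higher (adjusted p = 2.85e-05) and Prg3 at least 47.9-fold higher (adjusted p = 3.37e-05). Other genes with large rises were the phosphatase gene Dusp16 (6.74), the tetraspanin gene Cd9 (6.70), the lymphoid transcription factor gene Ikzf3 (6.53), the cytokine receptor gene Il31ra (6.43) and the TGF-beta co-receptor gene Tgfbr3 (6.24), with adjusted p from 1.10e-08 to 3.60e-05. The proteinase gene Mmp9 (5.06, adjusted p = 0.00209) and the receptor gene Trem1 (4.38, adjusted p = 0.00299) were higher. Large falls were seen for Ms4a8a (-7.65, adjusted p = 5.42e-05), Gas7 (-7.43, adjusted p = 0.000632) and the apelin receptor gene Aplnr, at the floor in SatM and at least 121-fold lower (adjusted p = 9.12e-05). Interferon-stimulated genes were lower, among them the antiviral genes Ifit1 (-4.97, adjusted p = 0.00385) and Rsad2 (-4.64, adjusted p = 0.0019).

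Of the sort markers, Msr1 (a scavenger receptor) measured 6.96 ± 0.69 (SD, n = 2) in SatM and 10.85 ± 0.13 (SD, n = 2) in inflammatory monocytes, a log2 difference of -3.89 (adjusted p = 0.000186). Ceacam1 measured 11.93 in SatM and 10.36 in inflammatory monocytes, and the log2 difference of 1.57 was not called (adjusted p = 0.0771). With the mean of its probe sets it was 2.21 (adjusted p = 0.00856), and in a fit of these 4 arrays alone the adjusted p was 0.00882. Csf1r (0.06), Cx3cr1 (0.92), Adgre1, which encodes F4/80 (0.69), and Cebpb (1.09) were not called (adjusted p from 0.139 to 1). For Cebpb the adjusted p was 0.0181 in the fit of these 4 arrays alone. Axl (-3.40), Ccl2 (-3.27), Flt3 (-2.73) and Thbs1 (-5.54) were lower (adjusted p from 0.0004 to 0.00487), with Flt3 at the floor in SatM. None of these 4 was called by limma once the bone marrow SatM array of the panel was added (adjusted p = 0.059, 0.0961, 0.121 and 0.351). In all, 1128 genes were called, 347 higher and 781 lower. The count was 552 without the first inflammatory monocyte array and 538 without the second. It was 0 with the replicate number as a block, a limma fit in which 3126 genes had an unadjusted p under 0.05. That fit leaves fewer residual degrees of freedom. Deviations of same-numbered arrays from their group means showed no likeness across genes (r = -0.05).

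By list, 11 of the 14 nonclassical monocyte genes were higher and 0 lower (13 and 0 adjusted over the list alone), with a median log2 difference of 3.95 (camera adjusted p = 8.44e-22). Of 21 interferon-stimulated genes, 14 were lower (18 adjusted over the list alone; median -2.61, adjusted p = 1.13e-12). Both calls held with an estimated correlation. Of 13 classical monocyte genes, 5 were lower (7 adjusted over the list alone; median -1.35, adjusted p = 3.97e-05; adjusted p = 0.192 with an estimated correlation). Of 8 eosinophil genes, 4 were higher (5 adjusted over the list alone; median 1.59, adjusted p = 3.68e-05; adjusted p = 0.125 with an estimated correlation). Immediate-early and stress genes (median 0.80, adjusted p = 0.00217; adjusted p = 0.619 with an estimated correlation) had 0 of 16 members called by limma over all genes and 4 adjusted over the list alone. Few members were called in the mature neutrophil list (2 of 12 higher, median 0.41, adjusted p = 0.0167; adjusted p = 0.526 with an estimated correlation) and the oxidative phosphorylation list (3 of 20 lower, 4 adjusted over the list alone, median -0.65, adjusted p = 0.017; adjusted p = 0.619 with an estimated correlation). Secondary and tertiary granule genes had 3 of 12 higher and 1 lower (6 and 3 adjusted over the list alone; median 1.53, adjusted p = 0.0441; adjusted p = 0.785 with an estimated correlation). That call was lost without the second inflammatory monocyte array (adjusted p = 0.0814) or the second SatM array (adjusted p = 0.178).

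The remaining 25 lists were not called between SatM and inflammatory monocytes. Among macrophage and activation lists, medians and adjusted p were 0.82 and 0.0646 for alveolar macrophage, -1.35 and 0.0608 for MHC class II presentation, -0.69 and 0.204 for fibrosis-associated, -0.50 and 0.239 for alternative activation, -0.18 and 0.388 for cytokine and chemokine, -1.62 and 0.156 for dendritic cell, and -0.05 and 0.862 for lysosome and phagocytosis genes. Alveolar macrophage genes were called without inflammatory monocyte array 1 (adjusted p = 0.0418), SatM array 1 (0.0409) or SatM array 2 (0.00878). MHC class II genes were called without inflammatory monocyte array 1 (adjusted p = 0.0117) or SatM array 2 (0.0414). Fibrosis-associated genes, with 3 higher and 5 lower of 15, were called as lower without SatM array 1 (adjusted p = 0.0208) or SatM array 2 (0.0323). Toll-like and Fc receptor genes (median -0.55), primary granule genes (-0.64), glycolysis genes (-0.22), cholesterol synthesis genes (-0.25), cell cycle genes (-0.20), ribosome biogenesis genes (-0.23) and myeloid transcription factor genes (-0.14) had adjusted p from 0.600 to 0.987. For the last 4 of these the test pointed up, against the sign of the median, and the mean was positive (0.10) for the transcription factors only. Lists with a median of 0.00 were sort and lineage surface, basophil and mast cell, tissue macrophage, stem and progenitor, B cell, T cell, NK cell, erythroid, megakaryocyte and platelet, and lung epithelium genes, and stromal genes had a median of 0.02 (adjusted p from 0.329 to 0.862). Within these, T cell and lung epithelium genes had means of -0.03 and -0.01 and a test pointing up.

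**Figure D2:**
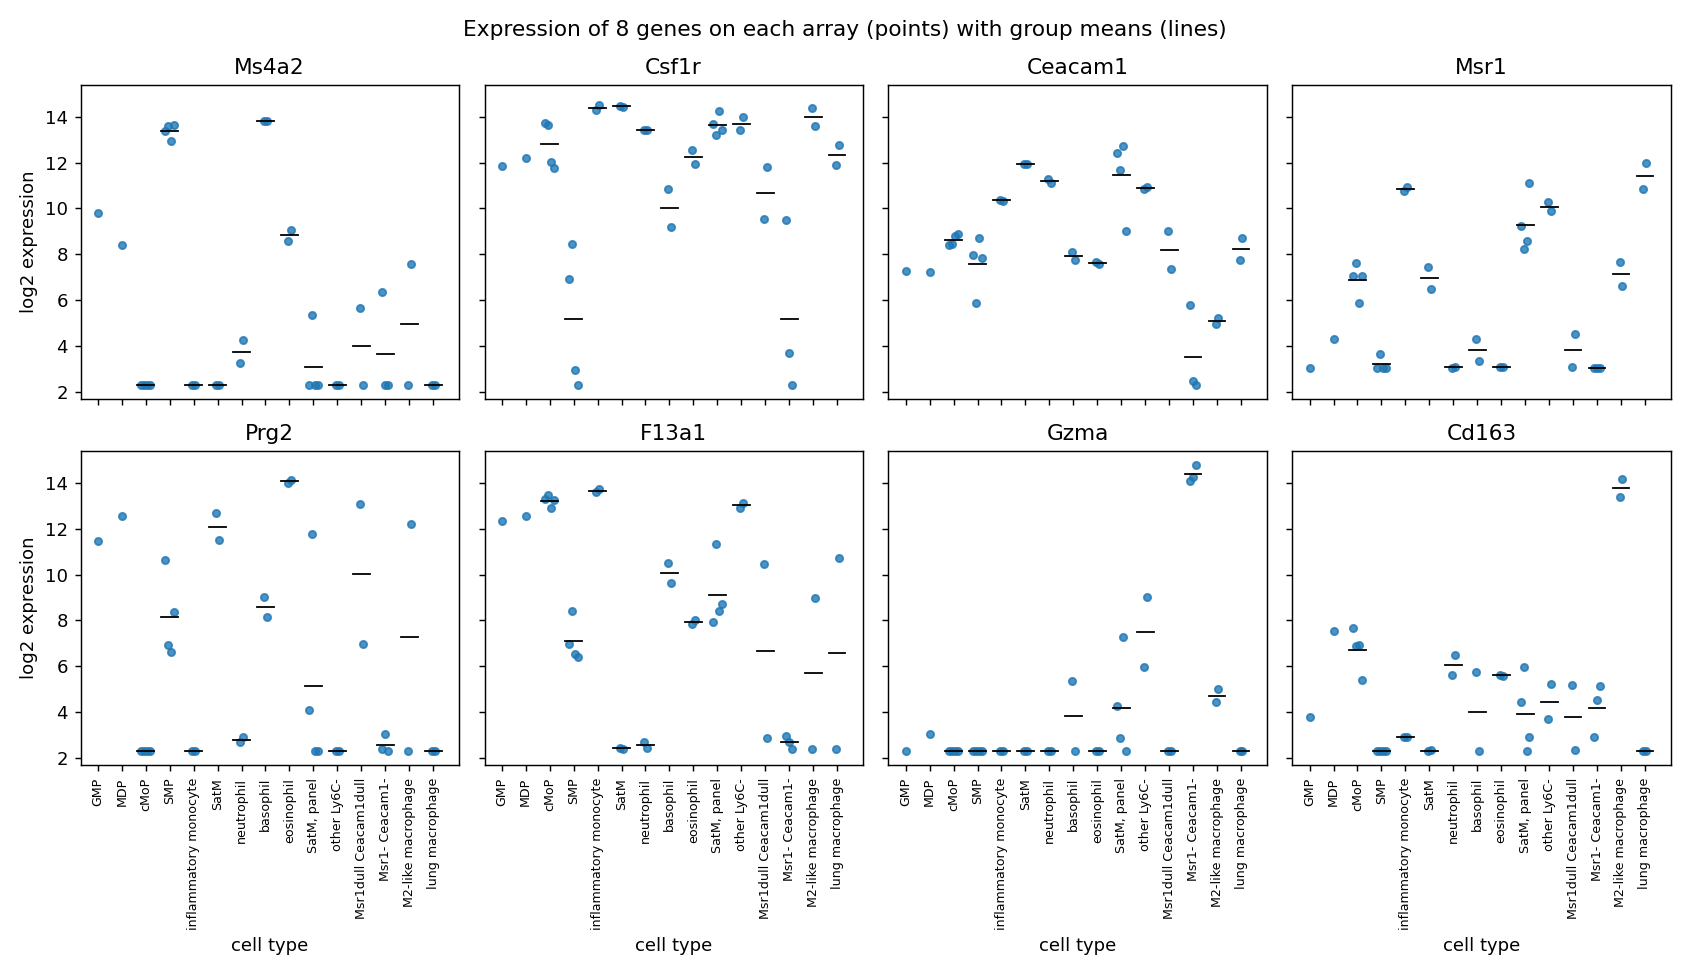
Log2 expression (y axis) of 8 genes on each array (points) by cell type (x axis), with lines for group means. Ms4a2 averaged 13.40 in SMP and lay at the floor in cMoP, and Prg2 averaged 12.10 in bone marrow SatM.

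The comparison of SMP with cMoP asked how the named SatM progenitor differs from the common monocyte progenitor. SMP held high mRNA levels of basophil and mast cell genes that lay at or near the floor in cMoP. The high-affinity IgE receptor genes Ms4a2 and Fcer1a measured 13.40 ± 0.32 (SD, n = 4) and 13.17 ± 0.46 (SD, n = 4), with all 4 cMoP arrays at the floor, and were at least 2200-fold and 1870-fold higher (adjusted p = 1.60e-11 and 1.93e-11). The transcription factor gene Gata2 measured 14.47 ± 0.27 (SD, n = 4) against 3.44 ± 0.60 (SD, n = 4), a log2 difference of 11.02. Mast cell carboxypeptidase (Cpa3), Cd200r3 and Cyp11a1 were at least 1280-fold, 1070-fold and 887-fold higher against the floor, and Cdh1 (11) and Csrp3 (9.90) were higher too. The adjusted p of these genes were 8.46e-09 or lower. Several monocyte genes were lower in SMP than in cMoP. The receptor gene Csf1r measured 5.16 ± 3.0 (SD, n = 4) against 12.80 ± 1.04 (SD, n = 4), a log2 difference of -7.64 (adjusted p = 4.30e-07). The transcription factor gene Irf8 differed by -7.71 (adjusted p = 2.44e-06), S100a4 by -10.10 (adjusted p = 2.16e-08), Ly86 by -8.98 (adjusted p = 2.61e-08), Fn1 by -7.50 (adjusted p = 5.46e-08) and Mgst1 by -7.48 (adjusted p = 4.84e-09). Tifab, at the floor in SMP, was at least 363-fold lower (adjusted p = 1.29e-07), and the granule protease gene Prtn3 differed by -8.11 (adjusted p = 7.74e-08).

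Progenitor surface genes differed as well. Flt3, at the floor in all SMP arrays, was at least 30.8-fold lower (adjusted p = 6.66e-08). Cd34 differed by -3.05 (adjusted p = 3.64e-05), Cx3cr1 by -4.61 (adjusted p = 2.20e-08) and Msr1 by -3.71 (adjusted p = 2.05e-06), while Kit (-0.98, adjusted p = 0.0933) and Cebpb (0.35, adjusted p = 0.429) were not called. The cytokine genes Il6 (7.97, adjusted p = 7.81e-07) and Csf1 (9.09, adjusted p = 6.32e-06) were higher in SMP. The eosinophil granule genes Prg2 and Epx, at the floor in cMoP, were at least 57.5-fold and 29.0-fold higher in SMP (adjusted p = 1.43e-05 and 1.12e-05). In all, 4285 genes were called, 1541 higher and 2744 lower. In the 4 arrays titled WT alone, 1359 genes were called, and Irf8 (adjusted p = 0.0611) and Cd34 (adjusted p = 0.0784) were not. Neither were Cdc6 (-3.37 over all 8 arrays; adjusted p = 0.0552 in the WT arrays), Cyc1 (-1.78; 0.244), H2-Aa (-5.22; 0.107) and Slc4a1 (5.48; 0.141).

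All 13 basophil and mast cell genes were higher in SMP, over all genes and adjusted over the list alone (median 9.02, camera adjusted p = 3.80e-16), which held with an estimated correlation. All 13 classical monocyte genes were lower (median -5.0, adjusted p = 8.61e-08; adjusted p = 0.109 with an estimated correlation). Eosinophil genes had 5 of 8 higher and 1 lower, and the same adjusted over the list alone (median 4.70, adjusted p = 0.00159; adjusted p = 0.237 with an estimated correlation). Ribosome biogenesis genes had 14 of 22 lower, such as Nhp2 (-4.06), with a median of -1.77 (adjusted p = 1.95e-05; adjusted p = 0.237 with an estimated correlation). Cell cycle genes had 19 of 33 lower, such as Mcm5 (-2.91), Hells (-3.44) and Prim1 (-3.15), with a median of -1.13 (adjusted p = 0.000219; adjusted p = 0.427 with an estimated correlation). Oxidative phosphorylation genes had 12 of 20 lower, such as Uqcrfs1 (-1.74), with a median of -1.17 (adjusted p = 1.95e-05; adjusted p = 0.260 with an estimated correlation). Lysosome and phagocytosis genes had 12 of 17 lower and 1 higher, with Psap (-4.13), Cd68 (-5.49) and Ctss (-6.85) among the falls and a median of -2.10 (adjusted p = 0.000219; adjusted p = 0.237 with an estimated correlation). These 4 counts were the same adjusted over the list alone.

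Immediate-early and stress genes had 11 of 16 higher and 2 lower in SMP, the same adjusted over the list alone, with Egr1 (4.09), Fosb (3.58) and Ier3 (6.07) higher and Atf3 (-4.46) lower (median 1.89, adjusted p = 0.000229; adjusted p = 0.427 with an estimated correlation). Erythroid genes had 6 of 10 higher and 1 lower, with Gata1, at the floor in cMoP, at least 68.5-fold higher (median 1.49, adjusted p = 0.0146; adjusted p = 0.427 with an estimated correlation). Megakaryocyte and platelet genes had 4 of 11 higher (median 0.50, adjusted p = 0.0108; adjusted p = 0.291 with an estimated correlation). Cholesterol synthesis genes had 8 of 16 lower and 1 higher (9 and 1 adjusted over the list alone; median -1.11, adjusted p = 0.0248; adjusted p = 0.291 with an estimated correlation). MHC class II presentation genes had 9 of 14 lower and 2 higher, with Ifi30 at -6.82 (median -3.57, adjusted p = 0.0331; adjusted p = 0.427 with an estimated correlation), a call that was lost without the first WT-titled cMoP array (adjusted p = 0.0628). Nonclassical monocyte genes were not called, with a median of 0.17, a mean of -0.68 and a test pointing up (adjusted p = 0.898).

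**Figure D3:**
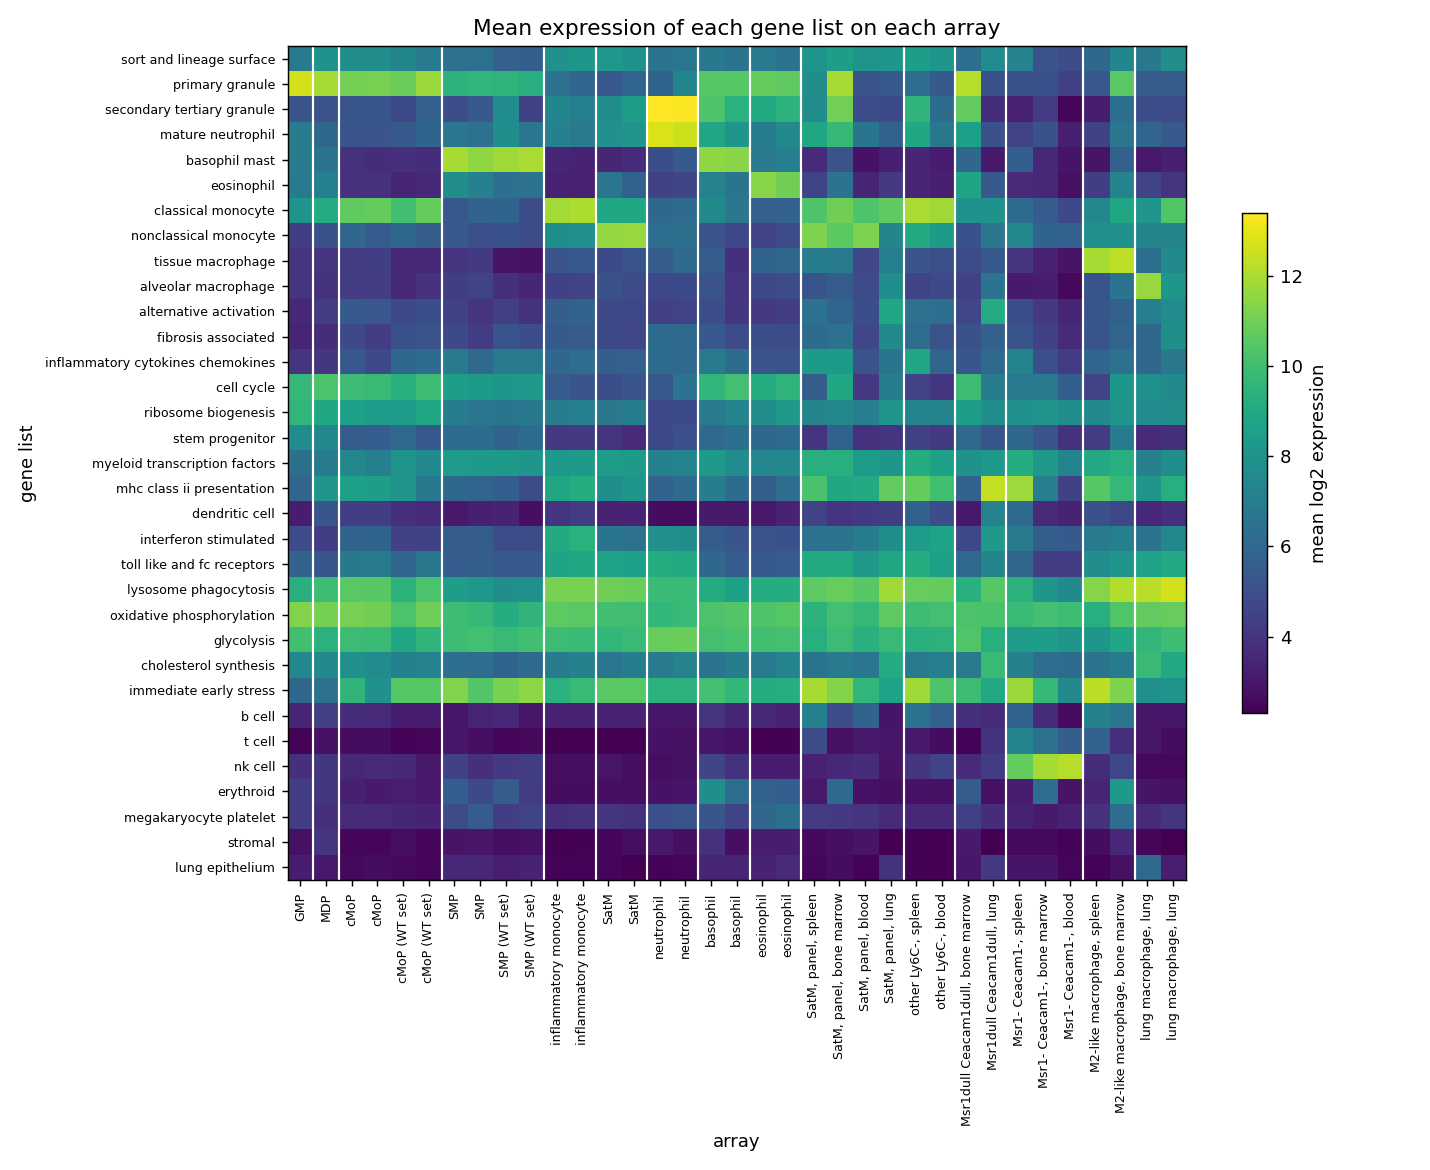
Mean log2 expression (colour) of the genes of each list (y axis) on each array (x axis, grouped by cell type and separated by white lines). The basophil and mast cell list is bright in SMP and basophils, and the NK cell list in Msr1-negative Ceacam1-negative cells.

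Whether the genes that set SMP apart from cMoP also set SatM apart from inflammatory monocytes was asked next. The comparisons used separate arrays but the same model. Of the genes called in both comparisons, 118 were higher in both (44.3 expected if the calls were independent) and 291 were lower in both (177.5 expected). Opposite directions were seen for 99 genes higher in SMP and lower in SatM (99.7 expected) and 42 genes lower in SMP and higher in SatM (78.8 expected). Within the same model the comparisons share each gene's error estimate and the filter. A gene with little spread is thus more easily called in both, so the calls were not independent. The expected numbers are therefore a rough reference, and the excess over them was not tested. The sum of 409 genes with a shared direction was 189 without the first inflammatory monocyte array, 182 without the second and 246 without the second SatM array. With the replicate number as a block it was 0, since limma then called 0 genes between SatM and inflammatory monocytes (3126 at an unadjusted p under 0.05). The 1541 genes higher in SMP ranked towards the SatM side (camera p = 0.0053, median 0.00), and with an estimated correlation p = 0.0247. The 2744 genes lower in SMP ranked towards the inflammatory monocyte side (median -0.38, p = 0.000204), and p = 0.113 with an estimated correlation.

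Against SMP, the mature SatM held far more mRNA of monocyte genes and far less of basophil and cell cycle genes. Group means were 14.46 ± 0.03 (SD, n = 2) and 5.16 ± 3.0 (SD, n = 4) for Csf1r, with a fitted log2 difference of 7.59 (adjusted p = 7.90e-06). Further rises were seen for the activation marker gene Cd83 (10.04), S100a4 (9.77), the stress gene Nupr1 (9.57), Treml4 (9.04), Apoc2 (8.44), Fcgr4 (8.07) and Cx3cr1 (7.23), with adjusted p from 7.59e-09 to 5.47e-05. Adgre1 (5.42), Ceacam1 (4.78), Msr1 (3.48) and Cebpb (2.81) were higher in SatM (adjusted p from 7.10e-06 to 0.000327). The basophil protease gene Mcpt8 (-11.29), Ms4a2 (-11.15), Gata2 (-11.10) and Fcer1a (-10.92) were lower (adjusted p from 1.04e-10 to 4.02e-09), with Ms4a2 and Fcer1a at the floor in SatM. The granule genes Ctsg (-10.15, adjusted p = 1.87e-07) and Mpo (-7.10, adjusted p = 0.00102), the progenitor gene Myb (-4.57, adjusted p = 4.18e-06) and Il6 (-8.96, adjusted p = 4.83e-06) were lower, with Il6 at the floor in SatM. In all, 3234 genes were called, 1548 higher and 1686 lower. In a fit of these groups alone 1686 were called in all. The count was 0 with the replicate number as a block, a limma fit with fewer residual degrees of freedom in which 2789 genes had an unadjusted p under 0.05.

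Nonclassical monocyte genes had 13 of 14 higher in SatM than in SMP (median 7.06, adjusted p = 3.02e-15), and basophil and mast cell genes had 12 of 13 lower (13 adjusted over the list alone; median -9.74, adjusted p = 5.76e-16). Both held with an estimated correlation. Cell cycle genes had 25 of 33 lower (26 adjusted over the list alone), such as Cdk1 (-6.06) and Ccnb2 (-6.02), with a median of -3.49 (adjusted p = 1.78e-13; adjusted p = 0.109 with an estimated correlation). Lysosome and phagocytosis genes had 12 of 17 higher and 1 lower, such as Cd68 (7.72) and Ctss (6.59), with a median of 2.29 (adjusted p = 2.97e-06; adjusted p = 0.109 with an estimated correlation). Toll-like and Fc receptor genes had 10 of 19 higher and 1 lower, such as Tlr7 (7.57), at the floor in SMP, and Clec7a (7.53), with a median of 1.63 (adjusted p = 1.03e-05; adjusted p = 0.109 with an estimated correlation). Classical monocyte genes had 9 of 13 higher and 1 lower (median 4.35, adjusted p = 0.000178; adjusted p = 0.167 with an estimated correlation).

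The parallel step from cMoP to inflammatory monocytes was marked by interferon-stimulated genes and by the loss of proliferation genes. Ifit3 (6.39, adjusted p = 8.14e-06), Ifit1 (6.05, adjusted p = 0.000335), Oasl2 (5.58, adjusted p = 5.69e-05) and the RNA sensor gene Ddx58 (5.23, adjusted p = 1.97e-07) were higher in inflammatory monocytes. The chemoattractant receptor gene Fpr2 (7.96, adjusted p = 0.000421), Msr1 (3.66, adjusted p = 9.89e-05), Adgre1 (2.84, adjusted p = 0.00431) and Cx3cr1 (1.70, adjusted p = 0.00349) were higher, and Csf1r was not called (-0.11, adjusted p = 0.998). Neutrophil granule genes Ctsg (-9.58), Mpo (-8.90) and Elane (-7.39), the replication gene Dtl (-8.16), Cd34 (-6.07), Myb (-5.11) and Flt3 (-2.11) were lower (adjusted p from 4.66e-08 to 0.00303). In all, 1795 genes were called, 799 higher and 996 lower. The count was 1028 without the first inflammatory monocyte array and 1003 without the second. Flt3 and Fcgr1 (3.76, adjusted p = 0.00313) were not called in a fit of cMoP and inflammatory monocytes alone (adjusted p = 0.0936 and 0.0826). Sox4 (-4.41, adjusted p = 0.000956) was not called with the mean of its probe sets (-0.76).

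Cell cycle genes had 32 of 33 lower in inflammatory monocytes than in cMoP, such as Cdc6 (-6.66), Hells (-6.47), Cdk1 (-6.38) and Prim1 (-6.22), with a median of -4.74 (adjusted p = 1.70e-32). Interferon-stimulated genes had 19 of 21 higher (median 3.42, adjusted p = 9.26e-19). Toll-like and Fc receptor genes had 12 of 19 higher (16 adjusted over the list alone; median 1.72, adjusted p = 2.47e-10), such as Tlr7 (5.64) and Fcgr4 (3.65). Nonclassical monocyte genes had 10 of 14 higher and 1 lower (11 and 2 adjusted over the list alone; median 2.37, adjusted p = 1.28e-07), such as Treml4 (4.62), Apoc2 (4.17) and Ace (a fitted 4.18), at the floor in cMoP. These 4 calls held with an estimated correlation. Ribosome biogenesis genes had 11 of 22 lower (12 adjusted over the list alone; median -1.36, adjusted p = 7.49e-08; adjusted p = 0.0815 with an estimated correlation). Primary granule genes had 7 of 9 lower (median -6.45, adjusted p = 2.36e-05; adjusted p = 0.0934 with an estimated correlation).

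The difference between the SMP-to-SatM step and the cMoP-to-inflammatory-monocyte step was tested directly as an interaction, in which 2688 genes were called, 1343 with a positive and 1345 with a negative difference between the steps. The interaction was positive for Il31ra (11.46), the ion transporter gene Slc12a2 (8.77), S100a4 (8.58), Itgax (7.71), Csf1r (7.70), Cx3cr1 (5.53), Pou2f2 (4.63) and Ceacam1 (2.61), with adjusted p from 3.98e-08 to 0.00937. It was negative for Ms4a2 (-11.10), Gata2 (-11.02), the complement receptor gene C3ar1 (-10.95), Fcer1a (-10.87), the chemokine receptor gene Ccr1 (-10.56), Rsad2 (-8.04), Ifit1 (-6.90) and Ddx58 (-6.73), with adjusted p from 4.40e-09 to 0.000723. Cebpb was not called (0.74, adjusted p = 0.411), and Msr1 (-0.18, adjusted p = 0.892) was called only with the mean of its probe sets (-2.30). Basophil and mast cell genes had 12 of 13 negative (13 adjusted over the list alone; median -7.57, adjusted p = 1.04e-17). Nonclassical monocyte genes had 12 of 14 positive (13 adjusted over the list alone; median 4.35, adjusted p = 1.93e-11), and interferon-stimulated genes had 11 of 21 negative (15 adjusted over the list alone; median -2.50, adjusted p = 1.56e-06). These 3 calls held with an estimated correlation. Ribosome biogenesis genes had 10 of 22 positive (16 adjusted over the list alone; median 1.82, adjusted p = 5.08e-05; adjusted p = 0.310 with an estimated correlation).

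The comparisons of SatM with spleen granulocytes asked how far SatM resembles these cells. Tissue and cell type changed together in these comparisons. Against neutrophils, 4336 genes were called, 2221 higher and 2115 lower. SatM held more mRNA of Nupr1 (9.78), the monocyte transcription factor gene Klf4 (9.49), Ms4a6c (9.27), the chemokine receptor gene Ccr2 (8.49), Cx3cr1 (7.39) and Msr1 (3.91), and Ace was at least 173-fold higher (adjusted p from 5.11e-12 to 3.15e-05). The neutrophil genes Arg2, Stfa3, Cxcr2, Il1r2 and Olfm4 were at the floor in SatM and at least 920-fold, 903-fold, 645-fold, 481-fold and 321-fold lower (adjusted p from 6.13e-11 to 4.03e-06). Ceacam1 was not called (0.72, adjusted p = 0.312), but was with the mean of its probe sets (1.81, adjusted p = 0.00788). Csf1r (1.04, adjusted p = 0.377) and Cebpb (-0.19, adjusted p = 0.878) were called only with the mean of their probe sets (2.3 and -1.51) or, for Csf1r, in the fit of SatM and neutrophils alone (adjusted p = 0.0023) or with the replicate number as a block (0.0156). Nonclassical monocyte genes had 13 of 14 higher in SatM (median 5.09, adjusted p = 1.02e-09), which held with an estimated correlation. Ribosome biogenesis genes had 15 of 22 higher and 1 lower (median 2.02, adjusted p = 3.14e-05; adjusted p = 0.358 with an estimated correlation). Mature neutrophil genes had 8 of 12 lower (9 adjusted over the list alone; median -3.29, adjusted p = 6.72e-06; adjusted p = 0.124 with an estimated correlation). Secondary and tertiary granule genes had 10 of 12 lower (median -5.26, adjusted p = 0.000163; adjusted p = 0.504 with an estimated correlation).

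Against basophils, 3425 genes were called, 1410 higher and 2015 lower in SatM. The sphingosine receptor gene S1pr5, at the floor in basophils, was at least 695-fold higher (adjusted p = 5.29e-08), and Treml4 (8.98), Apoc2 (8.46), Cx3cr1 (7.60), Ceacam1 (4.01) and Msr1 (3.15) were higher (adjusted p from 1.26e-08 to 0.000249). Cpa3, Ms4a2 and Fcer1a, at the floor in SatM, were at least 3060-fold, 2900-fold and 2800-fold lower, and Mcpt8 differed by -11.33 (adjusted p from 1.96e-10 to 1.15e-07). Basophil and mast cell genes had 12 of 13 lower (median -9.33, adjusted p = 4.68e-14) and nonclassical monocyte genes 13 of 14 higher (median 7.49, adjusted p = 1.10e-15), and both held with an estimated correlation. Cell cycle genes had 30 of 33 lower in SatM (median -4.64, adjusted p = 2.12e-17; adjusted p = 0.0696 with an estimated correlation). Of 19 Toll-like and Fc receptor genes, 12 were higher (median 3.39, adjusted p = 6.73e-07; adjusted p = 0.0696 with an estimated correlation). All 10 erythroid genes were higher in basophils than in SatM (median SatM minus basophil -3.92, adjusted p = 2.35e-06; adjusted p = 0.184 with an estimated correlation).

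Against eosinophils, 4429 genes were called, 1913 higher and 2516 lower in SatM. Apoc2 (10.26), Klf4 (8.67), Cx3cr1 (8.11), Ceacam1 (4.31) and Msr1 (3.88) were higher, S1pr5 was at least 695-fold higher, and Cebpb was not called (-0.19, adjusted p = 0.854). The called genes among these had adjusted p from 6.01e-09 to 3.67e-05. Eosinophil genes were lower in SatM, with differences of -9.53 for the lipoxygenase gene Alox15, -7.18 for Siglecf and -5.61 for Prg3, and falls of at least 180-fold for Il5ra and 391-fold for Gata1, at the floor in SatM (adjusted p from 3.14e-08 to 7.23e-06). Eosinophil genes as a list had 7 of 8 lower (median -5.12, adjusted p = 8.18e-06; adjusted p = 0.0713 with an estimated correlation). All 14 nonclassical monocyte genes were higher (median 7.76, adjusted p = 5.53e-14), which held with an estimated correlation. Cell cycle genes had 31 of 33 lower (median -4.33, adjusted p = 9.23e-14; adjusted p = 0.120 with an estimated correlation). Of 19 Toll-like and Fc receptor genes, 15 were higher (median 2.57, adjusted p = 1.22e-07; adjusted p = 0.0589 with an estimated correlation).

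SMP arrays correlated with basophil arrays at r = 0.933 to 0.973 across genes and with cMoP arrays at 0.860 to 0.899, and SMP was therefore compared with spleen basophils, a comparison added after the values were seen. It called 344 genes, 91 higher and 253 lower in SMP. Fcer1a (-0.54, adjusted p = 0.426), Cd34 (0.05, adjusted p = 1), Ccr2 (0.93, adjusted p = 0.110) and Cebpb (-0.07, adjusted p = 1) were not called. The transcription factor gene Fosl1, at the floor in basophils, was higher by a fitted 5.09 (adjusted p = 7.66e-05), and Neurl3 by 3.51 (adjusted p = 0.00138). The neutrophil granule genes Camp (-5.59, adjusted p = 0.00402) and Wfdc21 (-7.10, adjusted p = 0.00103) and S100a4 (-6.05, adjusted p = 0.00174) were lower in SMP. So were the monocyte genes Mgst1 (-4.98), Fn1 (-4.19), Csf1r (-3.13) and F13a1 (-2.61), with adjusted p from 0.000161 to 0.0497. These monocyte genes are given without alternatives. Erythroid genes were also among those called lower. Secondary and tertiary granule genes had 9 of 12 lower (12 adjusted over the list alone; median -4.21, adjusted p = 4.67e-13; adjusted p = 0.331 with an estimated correlation). Cell cycle genes had 2 of 33 lower (21 adjusted over the list alone; median -1.34, adjusted p = 3.97e-11; adjusted p = 0.331 with an estimated correlation), and basophil and mast cell genes were not called (median 0.21, adjusted p = 0.210). The basophil arrays themselves held neutrophil genes: 58 genes abundant in neutrophils and low in SMP lay a median of -4.43 from their neutrophil levels, with an interquartile range of 1.29, against a range of 3.19 in eosinophil arrays. The count was 138 without the first basophil array, 228 without the second and 527 without the first SMP array. In a limma fit of SMP and basophils alone 0 genes were called, with 1213 at an unadjusted p under 0.05.

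In the tissue panel, SatM was compared with Ly6C-negative cells that lacked both sort markers, in spleen, bone marrow and blood. The Msr1-negative Ceacam1-negative cells held high mRNA levels of NK cell genes. The cytotoxic granule gene Gzma averaged 14.38 ± 0.35 (SD, n = 3) in them and 4.17 ± 2.23 (SD, n = 4) in SatM (log2 difference -9.73, adjusted p = 0.000223). The transcription factor gene Tbx21 (-9.62), the receptor genes Klrk1 (-9.52) and Klra8 (-9.51), Gzmb (-9.49) and the chemokine gene Xcl1 (-9.35) were lower in SatM, with adjusted p from 8.16e-05 to 0.00191. Klrk1 and Xcl1 were at the floor in all 4 SatM arrays, and their values are fitted differences, not bounds. SatM held more mRNA of the sort marker genes Ceacam1 (8.66, adjusted p = 0.000572) and Msr1 (5.79, adjusted p = 0.000157). The chitinase-like gene Chil3 (10.28), haptoglobin (Hp, 9.72), Fpr2 (9.58), Mgst1 (9.24), Apoc2 (8.84), Fcgr4 (8.45), the lectin gene Clec4d (8.35) and Cebpb (6.46) were higher, with adjusted p from 6.43e-05 to 0.0022. Of these, Fpr2 and Mgst1 were at the floor in all 3 Msr1-negative Ceacam1-negative arrays, and their fitted differences are not bounds either. Ccr2 (-0.33, adjusted p = 0.914) and Itgax (-1.75, adjusted p = 0.333) were not called. In all, 1199 genes were called, 580 higher and 619 lower. The count was 631 without the bone marrow array of the Msr1-negative Ceacam1-negative cells, 614 without their blood array, 752 without the bone marrow SatM array and 447 without the blood SatM array. In a fit of these groups alone 117 genes were called, and Ceacam1, Fcgr4 and Gzma were not among them.

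None of the list calls of this comparison held with an estimated correlation. NK cell genes had 11 of 12 lower in SatM (median -9.38, adjusted p = 5.14e-16; adjusted p = 0.0542 with an estimated correlation). T cell genes had 6 of 13 lower (8 adjusted over the list alone), such as Thy1 (-5.34), with a median of -3.18 (adjusted p = 1.08e-05; adjusted p = 0.160 with an estimated correlation). Toll-like and Fc receptor genes had 12 of 19 higher (15 adjusted over the list alone; median 3.83, adjusted p = 1.38e-12; adjusted p = 0.0641 with an estimated correlation). Lysosome and phagocytosis genes had 10 of 17 higher (13 adjusted over the list alone), such as Ctsb (3.77), with a median of 2.12 (adjusted p = 4.54e-10; adjusted p = 0.172 with an estimated correlation). Classical monocyte genes had 8 of 13 higher and 1 lower (10 and 1 adjusted over the list alone; median 5.93, adjusted p = 2.06e-07; adjusted p = 0.114 with an estimated correlation). Nonclassical monocyte genes had 8 of 14 higher (9 adjusted over the list alone; median 4.66, adjusted p = 4.48e-07; adjusted p = 0.228 with an estimated correlation).

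SatM and other Ly6C-negative cells were compared across spleen and blood. Limma called 8 genes, with 1 higher and 7 lower, and 907 had an unadjusted p under 0.05. With 2 arrays of the other cells a low count is no proof of likeness: Flt3, with a fitted log2 difference of -5.58 (SE 2.48, adjusted p = 0.662), was not called. Group size alone does not set the count, since comparisons with as few arrays called 30 genes (Msr1-dull Ceacam1-dull cells) and 972 (M2-like macrophages). Rab36, a GTPase gene, was lower in SatM (-2.39, adjusted p = 0.00217). The 1 higher gene, Scnn1a, was named after its values were seen (3.71, adjusted p = 0.00217). Ceacam1 (1.56), Msr1 (-1.15), Ccr2 (-2.40), Csf1r (0.25) and Cx3cr1 (0.22) were not called (adjusted p from 0.592 to 1). Lists were called at the preset correlation only, and without called members: interferon-stimulated genes (median -1.96, adjusted p = 1.95e-10; adjusted p = 0.650 with an estimated correlation), nonclassical monocyte genes (1.98, adjusted p = 1.76e-07; adjusted p = 0.650 with an estimated correlation) and cell cycle genes (1.11, adjusted p = 5.91e-08; adjusted p = 0.885 with an estimated correlation). Adjusted over the list alone, 3 interferon-stimulated genes were lower and 1 nonclassical monocyte gene was higher. The gene count was 4 without the blood array of the other Ly6C-negative cells, and 3, 4, 2 and 17 without the spleen, bone marrow, blood and lung SatM array. In a limma fit of these groups alone it was 0, with 1952 genes at an unadjusted p under 0.05. Rab36 was not called with the stricter filter (adjusted p = 0.0775) or in the fit of these groups alone.

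Against Msr1-dull Ceacam1-dull cells of bone marrow and lung, 30 genes were called, 18 higher and 12 lower in SatM, and 2282 had an unadjusted p under 0.05. Msr1 averaged 9.29 ± 1.27 (SD, n = 4) in SatM and 3.80 ± 1.03 (SD, n = 2) in the dull cells (fitted log2 difference 5.85, adjusted p = 0.00343), but was not called with the mean of its probe sets (3.59, adjusted p = 0.0703). The inhibitory receptor gene Pilra (3.81, adjusted p = 0.00159) and the kinase gene Sgk1 (3.48, adjusted p = 0.00285) were higher and the actin regulator gene Enah (-3.34, adjusted p = 0.00159) was lower. Bst1 (4.30, adjusted p = 0.00159) was not called without the tissue term (adjusted p = 0.185). Ceacam1 (2.29, adjusted p = 0.229), Csf1r (2.63, adjusted p = 0.400) and Kit (-4.64, adjusted p = 0.209) were not called. Toll-like and Fc receptor genes had 1 of 19 higher (9 adjusted over the list alone; median 2.11, adjusted p = 7.86e-07; adjusted p = 0.478 with an estimated correlation), and classical monocyte genes had none called over all genes and 6 of 13 higher adjusted over the list alone (median 2.75, adjusted p = 4.76e-05; adjusted p = 0.520 with an estimated correlation). The 2 dull arrays correlated at r = 0.868 across genes, and the bone marrow one correlated with eosinophil arrays at 0.952 and 0.956 and with the SatM arrays of the panel at 0.871 to 0.928. The count was 135 without the bone marrow dull array, 1845 without the lung one, and 7, 5, 12 and 1841 without the spleen, bone marrow, blood and lung SatM array. In a limma fit of these groups alone it was 0, with 344 genes at an unadjusted p under 0.05.

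Against M2-like macrophages of spleen and bone marrow, 972 genes were called, 342 higher and 630 lower in SatM. The haemoglobin scavenger receptor gene Cd163 averaged 13.78 ± 0.54 (SD, n = 2) in the macrophages and 3.90 ± 1.64 (SD, n = 4) in SatM (fitted log2 difference -9.36, adjusted p = 0.00099). Slc16a9 and Stab2, at the floor in all 4 SatM arrays, were lower by a fitted -9.33 and -8.44 (adjusted p = 2.98e-06 and 2.38e-07), and Slco2b1 (-9.05) and the growth factor gene Igf1 (-7.25) were lower (adjusted p = 0.000259 and 0.000649). Chil3 (8.07), Plekhg1 (7.21), Ldlrad3 (7.14), Ceacam1 (7.13), the lactate transporter gene Slc16a3 (6.11) and the integrin gene Itgal (4.68) were higher in SatM (adjusted p from 0.000253 to 0.00626). Pdgfc (-8.72), Axl (-8.18) and Trem3 (6.34) were called, but not without the tissue term (adjusted p = 0.0914, 0.169 and 0.243). Msr1 (1.72, adjusted p = 0.0556) was called with the stricter filter (0.0459), the filter at log2 5 (0.043) or without the lung arrays (1.58, adjusted p = 0.0383). Csf1r (-0.22, adjusted p = 0.967) and Adgre1 (-1.21, adjusted p = 0.688) were not called. Tissue macrophage genes had 12 of 18 lower (16 adjusted over the list alone; median -6.91, adjusted p = 1.63e-10; adjusted p = 0.0981 with an estimated correlation). Mature neutrophil genes had 4 of 11 higher (5 adjusted over the list alone; median 4.10, adjusted p = 6.83e-06; adjusted p = 0.131 with an estimated correlation). Their mean was 8.82, 9.76, 6.63 and 5.74 in spleen, bone marrow, blood and lung SatM, against 4.47 and 6.66 in spleen and bone marrow macrophages. Nonclassical monocyte genes had 4 of 14 higher (5 adjusted over the list alone; median 2.88, adjusted p = 0.000445; adjusted p = 0.572 with an estimated correlation). The count was 350 and 418 without the spleen or bone marrow macrophage array, and 433, 505 and 633 without the spleen, bone marrow or blood SatM array. In a limma fit of these groups alone it was 0, with 2831 genes at an unadjusted p under 0.05.

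Whether the SatM signature of the bone marrow arrays was seen in the separate panel arrays was tested on SatM against Msr1-negative Ceacam1-negative cells. Of the genes higher in SatM than in inflammatory monocytes, 344 were measured in the panel, with a median log2 difference of 0.49, and 61.6% were positive, against 44.9% of all genes (camera p = 2.23e-08; p = 0.184 with an estimated correlation). Of these, 73 were called higher and 4 lower. The median was 0.31 without SatM array 1 and 0.92 without inflammatory monocyte array 2. The 776 genes lower in SatM had a median of 0.04, with 50 called higher and 59 lower, and were not called as a set (camera p = 0.219; p = 0.682 with an estimated correlation). At the preset correlation this set was called as moving up, with camera p of 0.0314, 0.0252 and 0.0292, without inflammatory monocyte array 1 (median 0.19), inflammatory monocyte array 2 (0.21) or the spleen array of the Msr1-negative Ceacam1-negative cells (0.19). With the top 200 genes it was called at the preset correlation (median 0.29, p = 0.0107; p = 0.389 with an estimated correlation). Of these, 61.6% were positive, against 63.8% of the top 200 higher genes. The comparison cells held NK cell genes and less Csf1r (5.15, against 13.64 in SatM of the panel). Genes that SatM shares with other monocytes can therefore rise here as well. For this reason the test cannot tell a SatM signature from a monocyte one.

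GMP and MDP had 1 array each, and their values carry no error. In GMP and MDP, the granule genes Mpo (14.37 and 13.80) and Elane (12.42 and 11.58) were measured at high levels. Kit (8.03 and 6.79) and Cd34 (11.51 and 11.13) were measured in both, and Flt3 at 4.14 in GMP and 9.59 in MDP. Prg2 was measured at 11.47 and 12.57, Ms4a2 at 9.78 and 8.40, and Mcpt8 at 11.98 and 12.17. In lung, the array titled as macrophages had the alveolar macrophage genes Car4 at 12.05 and Siglecf at 11.35, against 6.50 and 7.26 in lung SatM and 6.67 and 6.00 in the F4/80-positive cells. Arg1 measured 3.01 in that array, 10 in lung SatM and 11.88 in F4/80-positive cells, and C1qb measured 8.73, 14.19 and 14.18. Lung SatM correlated across genes at r = 0.986 with the F4/80-positive array and 0.956 with the other lung macrophage array. Msr1 measured 11.09 in lung SatM, 4.53 in Msr1-dull Ceacam1-dull cells of the lung, 10.83 in the lung macrophages and 11.99 in the F4/80-positive cells. The dull cells had the dendritic cell genes Zbtb46 at 12.28, Flt3 at 10.36 and Itgae at 11.86, against 6.70, 2.77 and 3.56 in lung SatM.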

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

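All tests of explanations in this part were chosen after the result was seen. 2 kinds of result are collected here: differences between the SMP-to-SatM step and the cMoP-to-inflammatory-monocyte step that passed a test of the difference itself, and single arrays far from the other arrays of their group by Dixon's test in groups of 4.

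In the test of the difference between the steps, 2688 genes were called. Basophil and mast cell genes had a median of -7.57, because they were high in SMP and low in the other 3 groups. Cells like those of the basophil arrays, as a minority of the SMP sort, would put these genes at least 1 log2 unit lower in SMP. This holds if the other cells lack these genes. The median difference was 0.21 (interquartile range 0.80), which argues against such a minority. The basophil arrays also held cell cycle genes (means 9.61 and 10.1, against 5.4 and 6.51 in neutrophils) and erythroid genes (7.83 and 6.3). They may therefore not hold basophils alone, and a minority of pure basophils in the SMP sort stays open. Basophils of the marrow as most of the sort and a progenitor that expresses these genes itself also stay open and were not tested.

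The other lists called between the steps at the preset correlation had medians of 4.35 for nonclassical monocyte, -2.50 for interferon-stimulated, 1.82 for ribosome biogenesis, 1.77 for lysosome and phagocytosis, -1.45 for cytokine and chemokine, and 0.99 for cell cycle genes. With an estimated correlation the first 2 calls held, as did that of the basophil and mast cell genes, and the last 4 were lost (adjusted p = 0.310, 0.328, 0.328 and 0.679). No explanation was tested for these.

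Of 267 group-and-item pairs tested for a stray array, 40 (15%) had one, 13 of 99 for list means and 27 of 168 for genes, where chance gives about 1 in 20 (5%). The genes share arrays and are not independent. The 5% also assumes normal values and arrays that differ by chance alone. Arrays of a group came from different sets or tissues. Where the other arrays tie at the floor, as for Kit (6.95) and Gzmb (2.57) in bone marrow SatM, any higher value is flagged. The 15% therefore cannot be read as an excess of stray arrays. The genes tested were those of the text, chosen after the values were seen, and the share moves with that choice.

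Among cMoP, the first WT array was lowest for the means of classical monocyte genes (10.03, others 10.71 to 10.8), Toll-like and Fc receptor genes (5.91), Cdk1 (9.43), Fn1 (10.06) and Psap (12.81), and highest for stromal genes (2.73) and Gata2 (4.35). The second WT array was lowest for NK cell genes (3.06) and H2-Aa (7.07) and highest for Nhp2 (8.88) and Treml4 (3.14). The first array without WT in its title was lowest for Cdh1 (2.3).

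Among SMP, the first WT array was highest for mature neutrophil genes (7.82), Camp (10.11), S100a4 (4.42) and Wfdc21 (5.72), and lowest for stem and progenitor genes (5.84). SMP array 2 was lowest for cytokine and chemokine genes (6.14) and highest for Ly86 (4.58), Msr1 (3.66) and Nupr1 (4.06). SMP array 1 was highest for Cx3cr1 (4.42).

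Among SatM of the panel, the lung array was highest for cholesterol synthesis (9.15) and lung epithelium genes (3.93), Bst1 (10.58), Enah (3.97), Pdgfc (10.79) and Slco2b1 (4.71). It was lowest for Cebpb (8.58), Fcgr4 (9.1), Fpr2 (8.98) and Ldlrad3 (7.66). The bone marrow array was highest for stem and progenitor (5.77) and erythroid genes (6.09), Gzmb (2.57) and Kit (6.95). The spleen array was highest for T cell genes (4.91) and Thy1 (3.44). The blood array was lowest for tissue macrophage genes (4.66) and highest for Rab36 (2.79). The spleen, blood and lung arrays are the only SatM arrays of their tissue, so tissue and array cannot be told apart there. The other bone marrow SatM arrays had Kit at the floor (2.3) and lower means of stem and progenitor (3.95 and 3.61) and erythroid genes (2.77 and 2.72). These high values were thus not shared by SatM of the same tissue. Lists that were not flagged differed too: primary granule genes averaged 11.96 in the panel array, against 5.38 and 5.91. Cell cycle genes averaged 8.97, against 4.99 and 5.22, and nonclassical monocyte genes 10.59, against 11.59 and 11.68. This array enters all panel comparisons and the fit that adds it to the other SatM arrays.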

How the results depend on the processing

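The filter at log2 5 and the fit without the lung arrays were chosen after the results were seen, as was the comparison of SMP with basophils. Each alternative changed 1 choice, except that the one for the variance model left out the trend and added robust estimation together. With 1 array left in a group, that array was assumed to vary like those of the other groups. The alternatives for a pseudocount apply to linear values and were not run. The causes of the changes below were not tested. Fits with the replicate number as a block or of the compared groups alone leave fewer residual degrees of freedom. A call lost there can reflect lost power.

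With the correlation between list genes estimated, 16 list calls of the planned comparisons held, of 137. The SatM signature in the panel, with a median of 0.49, was not called (p = 0.184 with the estimated correlation).

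With every probe set tested by itself, probe sets called were 2584 for SatM against inflammatory monocytes, 8358 for SMP against cMoP, 6459 for SatM against SMP, 3024 for inflammatory monocytes against cMoP, 4959 for the interaction, 8965, 6884 and 9250 against neutrophils, basophils and eosinophils, 601 for SMP against basophils, and 2100, 19, 50 and 1673 for SatM of the panel against Msr1-negative, other Ly6C-negative, Msr1-dull and M2-like cells.

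With the replicate number as a block, limma called 0 genes for SatM against inflammatory monocytes (3126 at an unadjusted p under 0.05) and 0 for SatM against SMP (2789), and so 0 with a shared direction. In fits of the compared groups alone, limma called 0 genes for M2-like (2831 at an unadjusted p under 0.05), 0 for Msr1-dull (344), 0 for other Ly6C-negative cells (1952), 0 for SMP against basophils (1213), 117 for Msr1-negative cells and 1686 for SatM against SMP.

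Without the filter, counts were 732 for Msr1-negative, 4 for other Ly6C-negative, 6 for Msr1-dull and 555 for M2-like cells, and 212 for SMP against basophils. The stricter filter gave 2 for other Ly6C-negative cells. The filter at log2 5 gave 49 for Msr1-dull cells and 0 in limma for other Ly6C-negative cells (773 at an unadjusted p under 0.05). Without the tissue term 579 were called for M2-like cells, and in the 4 WT-titled arrays alone 1359 for SMP against cMoP.

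Leaving out each array in turn gave 538 to 892 genes for SatM against inflammatory monocytes, 1003 to 1833 for inflammatory monocytes against cMoP, 138 to 527 for SMP against basophils, 447 to 1440 for Msr1-negative, 2 to 17 for other Ly6C-negative, 5 to 1845 for Msr1-dull and 350 to 1312 for M2-like cells, and 182 to 429 with a shared direction. Genes of the signature lower in SatM were called as moving up with a fit of the compared groups alone (median 0.04) and with the top 200 genes (0.29, p = 0.0107; p = 0.389 with an estimated correlation; 61.6% positive, against 63.8% of the top 200 higher genes), and their median ran from -0.18 to 0.21 when each array was left out.

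By the rule used, a count, or a list not called as reported, could not be labelled as reversed. Among the other results 0 were reversed over all alternatives. Of counts, 63 moved by more than 1.5 times and 196 did not. For lists, 245 alternatives ended a call, 242 made one and 6814 did neither. The genes of the text, other than those given without alternatives, were chosen so that their call held when each array was left out. Those alternatives therefore say nothing about them. In the other alternatives the numbers for genes were 103, 12 and 2675.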

Other observations

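All tests of explanations in this part were chosen after the result was seen, except the splits of the arrays, and the tests on the Msr1-negative Ceacam1-negative cells were divided by tissue with their values known.

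The Msr1-negative Ceacam1-negative arrays held NK cell genes at high levels. Monocytes like those of the other Ly6C-negative sorts as most of the cells would leave 8 monocyte genes at most 1 log2 unit lower. Their median was -6.44 or lower in bone marrow and blood and -2.76 in spleen, which argues against it. NK cells may be most of the sort from bone marrow and blood, where at least 11 of the 12 NK cell genes were among the highest 10% of genes, against at most 2 in arrays of other sorts. In spleen 8 were, between the numbers set for and against. A smaller share of NK cells beside cells other than monocytes stays open in all 3 tissues. T cell genes such as Thy1 were also higher than in SatM, but whether NK cells carry them was not tested. MHC class II presentation genes averaged 11.79 in the spleen array, against 7.07 in bone marrow and 4.43 in blood. Dendritic cell genes averaged 6.17, against 3.62 and 3.35. Tissue differences were not tested.

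Eosinophil granule genes were present in the 2 bone marrow SatM arrays outside the panel. Means of the eosinophil list were 6.67 and 5.76 there and 6.53 in the bone marrow SatM array of the panel. They were 8.78, 7.29 and 3.56 in the Msr1-dull, M2-like and Msr1-negative arrays of the bone marrow. SatM of spleen, blood and lung had 4.54, 3.47 and 4.14. High means were therefore not particular to SatM among the bone marrow sorts. Eosinophils like those of the spleen arrays, at the share given by Prg2 (25.4% of its eosinophil level), would bring other eosinophil genes to set levels. The 8 genes tested missed these levels by a median of -5.59. The medians were -3.04 at the share given by Epx (4.06%) and -2.14 at that given by Prg3 (2.04%). Cell cycle genes averaged 9.18 and 9.51 in the spleen eosinophil arrays, against 5.40 and 6.51 in neutrophils. These arrays may therefore not stand for mature eosinophils. Free marrow RNA in every marrow sort would put Prg2 over the floor in inflammatory monocyte and cMoP arrays. It was over the floor in 0 of 6 arrays. The bone marrow arrays of the panel were not part of this test. Prg2 averaged 12.1 in SatM and measured 11.47 and 12.57 in the GMP and MDP arrays. To explain it, cells like GMP and MDP would have to be about all of the SatM sort. The 10 other GMP and MDP genes tested missed the levels needed for this by a median of -8.73. The test does not cover progenitors with more Prg2. These values argue against eosinophils like those of the spleen arrays, free RNA in every marrow sort, and cells like GMP and MDP. Eosinophils of another stage, mature or precursor, in the sort or expression by SatM may explain the genes, and none of these was tested.

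Neutrophil genes were measured in the basophil arrays. Neutrophil RNA in these arrays may be the source: 58 genes abundant in neutrophils and low in SMP lay a median of -4.43 from neutrophils with an interquartile range of 1.29. It does not account for most of the genes lower in SMP than in basophils, since 89 of the 253 (35.2%) were higher in neutrophils than in basophils, against 43% of all genes tested.

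Of the 35 splits of the 8 SMP and cMoP arrays into groups of 4, 1 called as many genes as the real one (itself, 4285). Every other split puts both cell types into each group, which widens the spread within groups. Only 8 splits part all 4 numbered pairs. The test therefore cannot exclude chance. The highest other count was 564, from the split by the WT-titled set, and among the 8 splits that part all 4 numbered pairs the highest other was 7. Of the 35 splits of the 7 panel arrays of SatM and Msr1-negative Ceacam1-negative cells, 1 called as many (itself, 1199), with 527 the highest other, from the split that moves lung SatM to the other group.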
